A study of Mus musculus with 5 samples.

How the data were processed

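The data are 10x Genomics droplet counts of nuclear RNA from the septal complex of 30 mice (C57bl/6J, 8 weeks), 6 mice pooled in each of 5 libraries and 1 library per group. Per the labels, brains were perfused and held in solutions with blockers of neuronal firing, transcription and translation (TTX, APV, DNQX, actinomycin and anisomycin), and the dissection was meant to limit tissue from the nucleus accumbens. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger on mm10, with no further scaling stated by the authors. Per the file headers, the saline, chronic morphine and withdrawal matrices came from version 3.1.0 with 31053 genes, and both acute matrices from Cell Ranger 4 with 32285 genes, while the submitters' notes name versions 3.1.0 and 6.1.2. Per the labels, the first 3 libraries used Chromium 3' version 3 chemistry on a HiSeq instrument and the acute libraries NextGEM chemistry on a NovaSeq instrument. Whether intronic reads were counted, and how strand was used, is not stated. Each matrix lists every barcode (6794880 in each of the first 3, 3121627 in acute morphine and 2701813 in acute naloxone), so nuclei were called here.

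Only the 30406 genes with an identifier in all 5 tables were used; the others held 0.82%, 1.01%, 1.11%, 1.76% and 1.82% of UMIs in saline, chronic morphine, withdrawal, acute morphine and acute naloxone. A barcode was kept as a nucleus with at least 1000 UMIs, at least 700 genes and at most 5% mitochondrial UMIs. Scrublet scores (scanpy 1.11.5) were computed per library, and the highest-scoring share, set at 0.8% per 1000 nuclei, was removed as doublets (1009, 927, 1155, 536 and 467 nuclei). The tool's own threshold, not used, marked 0, 0, 3419, 503 and 604. Nuclei of all libraries were clustered together on 2000 variable genes, scaled within library, with 30 components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2), leaving immediate early, late activity, glucocorticoid-responsive, heat shock, circadian, mitochondrial, ribosomal and sex-linked genes out of the variable genes. The 35 clusters were named by marker lists, needing at least 3 markers in at least 20% of nuclei, and septal GABAergic clusters were clustered again at resolution 0.8 into 27 sub-clusters. Of these, 4 led by genes of other classes or with high doublet scores were left out of the septal class, and 22 had at least 50 nuclei in every library. Nts is one of the septal markers and took part in the clustering, so sizes of Nts sub-clusters are not compared. A nucleus was called female with Xist and no Y-linked UMI, and male with the reverse. Female nuclei were 43.7%, 45.4%, 43.0%, 43.3% and 28.8% of each library and male nuclei 30.6%, 30.9%, 31.5%, 36.5% and 36.1%. Nuclei with both kinds of UMI were 13.8%, 11.8%, 9.91%, 3.97% and 4.31%, and those with neither 11.99%, 11.95%, 15.6%, 16.2% and 30.8%. The share of wrong sex calls was not estimated and may differ between libraries.

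UMIs were summed over the nuclei of a class in a library and divided by the class total (CPM). The 5 classes with at least 200 nuclei in every library were compared. CPM values carry exact Poisson intervals, log2 ratios exact conditional binomial (Clopper-Pearson) intervals, and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. Log2 ratios used 0.5 UMI added to each count. Against a library without a UMI, a fold was given as a lower bound with 3 counts as the floor. With 1 library per group no test was made, no p-value was computed and genes were not counted as changed.

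Fixed lists of genes, 14 in all, were rapid immediate early, late activity, glucocorticoid-responsive, opioid system, cyclic AMP and protein kinase A, septal peptide, septal neuromodulator receptor, synaptic receptor, heat shock, circadian, cholesterol synthesis, myelin, reactive astrocyte, and microglia and inflammation genes. Each was given as the median log2 ratio of members with at least 50 UMIs over both libraries, as summed CPM, and as a percentile among 10000 random lists matched on mean expression. Matching on gene length as well (GENCODE M21 gene spans, known for 30329 of the genes) was chosen after a trend with length had been seen, and the percentiles in the text are the length-matched ones. Percentiles describe these libraries and are not tests.

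Genes were named by a rule. In septal GABAergic neurons these were the 8 highest and 8 lowest eligible genes of each comparison, up to 4 members of each fixed list with the largest log2 ratio in either direction, and Fos, Junb, Nr4a1, Npas4, Nts, Oprm1 and Penk. In the other classes they were the 3 highest and 3 lowest eligible genes. An eligible gene had at least 50 UMIs over both libraries, at least 20 CPM in the higher one, the same direction in female and male nuclei, a level at least 25% of that in the class with the highest level, and was not mitochondrial, ribosomal, haemoglobin, sex-linked or known by a clone name only. Other genes named in the text, Homer1 and Fkbp5 in septal sub-clusters and list members in other classes among them, were chosen after their values were seen.

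Filters, lists, the naming rule, comparisons and most alternatives were chosen before the data were examined. The alternatives were other depth minimums (500 and 2000 UMIs), median-of-ratios scaling, equal weight for clusters, subtraction of ambient RNA (profile of barcodes with 10 to 100 UMIs), female or male nuclei alone, doublets kept, 5 UMIs added, nuclei thinned to 1000 or 2000 UMIs, clustering resolution 2, and list minimums of 10 and 200 UMIs. Ambient RNA from barcodes with over 100 to 400 UMIs, where empty droplets lie, Malat1 left out, the 4 sub-clusters kept, and length-matched lists were added after the data were seen, as was the following of astrocyte sums. Ambient-subtracted values with 3 or fewer counts left were omitted, a rule also made later. Checked on data simulated from the septal counts with counting error alone, intervals held the true value for 95.7% of unchanged genes. That check covers the calculation and not the spread between libraries or mice. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.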

Results

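Nuclear RNA of the mouse septal complex was counted nucleus by nucleus in 5 droplet libraries, 1 per treatment group, each pooled from 3 male and 3 female mice. Per the labels, collection was 1 hour after the final dose in every group. The groups were saline (14 saline injections over 7 days), chronic morphine (14 morphine injections over the same days), precipitated withdrawal (the morphine course followed after 1 hour by 1 mg per kg naloxone, an opioid receptor antagonist), acute morphine (13 saline injections and 1 of 10 mg per kg morphine) and acute naloxone (13 saline injections and 1 of 1 mg per kg naloxone). Total unique molecular identifiers (UMIs) in the deposited tables were 80059183, 81407930, 80645062, 56449197 and 42994857 in that order. The filters kept 10221, 9838, 10863, 7650 and 7171 nuclei, against the approximately 10000 captured per group that the study's design text states. Median UMIs per kept nucleus were 4514, 5160, 4327, 4271 and 3204, and median genes were 2349, 2419, 2122, 2233.5 and 1808. Each group has 1 library, so no difference here has a replicate check, no test was possible, and the intervals (95%) cover counting error only. The saline, chronic morphine and withdrawal libraries shared a chemistry, sequencer and software version that differed from those of both acute libraries.

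Septal GABAergic neurons, the inhibitory projection cells that make up most of the lateral septum, were the most abundant named class in every library. They formed 44.3% of nuclei in saline, 46.3% in chronic morphine, 39.7% in withdrawal, 50.1% in acute morphine and 47.2% in acute naloxone. Class names throughout stand for nuclei that resemble a cell type by markers fixed in advance. Astrocytes made up 15.5%, 12.02%, 14.1%, 15.4% and 13.6% of nuclei in the same order, and 10.7%, 8.32%, 7.39%, 9.34% and 2.55% among nuclei with at least 2000 UMIs. Oligodendrocytes made up 9.26%, 9.52%, 10.8%, 9.05% and 6.05%, and Slc17a6 glutamatergic neurons 3.09%, 4.31%, 4.62%, 3.58% and 3.88%. Microglia were 2.60%, 2.35%, 2.01%, 1.91% and 0.725%. Clusters left without a name held 14.2%, 15.5%, 15.6%, 9.73% and 18.4% of nuclei. Among them was a cluster of 1206 nuclei (282, 236, 284, 237 and 167) with 5 oligodendrocyte markers detected. It was left unnamed because more of its leading genes belonged to another class, so the oligodendrocyte shares do not include it. Neurons resembling striatal projection neurons were 4.60% of the withdrawal library (95% exact binomial interval 4.22 to 5.01) and 2.07%, 2.02%, 1.93% and 1.53% of the saline, chronic morphine, acute morphine and acute naloxone libraries. Of the 500 such nuclei in withdrawal, 147 came from a cluster led by Tac1, Gpr149 and Drd3 that held 9 to 13 nuclei in each other library. Median UMIs of septal GABAergic neurons were 5945, 6596, 5967, 6396 and 4313.

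The comparison of chronic morphine with saline asked how septal cells differed after 7 days of morphine. Collection was 1 hour after the last dose, so effects of that dose and of the course cannot be told apart. In septal GABAergic neurons, rapid immediate early genes, which neurons switch on within minutes of activity, were lower in the chronic morphine library. Of 25 measured members of the 30-gene list, 24 were lower, and their summed level was 421 CPM (UMIs of the genes scaled to the total of the class) against 595 (log2 ratio -0.50, 95% interval -0.53 to -0.47). Junb was 23.3 against 59.3 CPM (log2 ratio -1.34, interval -1.47 to -1.22), and Fos, whose protein pairs with Jun proteins in the AP-1 factor, was 5.22 against 12.9 CPM (-1.31, interval -1.58 to -1.04). The neuropeptide gene Nts, encoding neurotensin, was 45.7 against 103 CPM (-1.18, interval -1.27 to -1.09), while the mu opioid receptor gene Oprm1 was higher at 71.0 against 51.9 CPM (0.45, interval 0.36 to 0.55). Short genes as a whole were also lower: with genes split by length into 5 groups of equal size, the median log2 ratio was -0.59 in the shortest group and 0.13 in the longest, and the list's median of -0.63 lay at percentile 9.59 of 10000 random lists matched on gene length and expression.

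Other activity genes ranged widely between chronic morphine and saline. Egr4, Btg2, Nr4a1 and Npas4, all transcription regulators induced by activity, had log2 ratios of -1.65, -1.31, -0.55 and -0.44. The late activity list had 11 of 20 members higher and a median of 0.14 (length-matched percentile 95.9). It held Inhba, a subunit of activin, at 77.6 against 23.1 CPM (log2 ratio 1.74, interval 1.62 to 1.87), and Vgf, a secreted peptide precursor, at 61.4 against 108 CPM (-0.81, interval -0.90 to -0.73). Inhba overlaps an annotated antisense gene, and strand use in counting is not stated, so its level is uncertain.

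Neuropeptide genes were lower in the chronic morphine library than in saline. Of 12 measured septal peptide genes 11 were lower, with a median log2 ratio of -1.02 (length-matched percentile 0.11) and a summed level of 147 against 302 CPM. Cartpt, encoding the CART peptide, was 11.7 against 33.9 CPM (log2 ratio -1.53, interval -1.71 to -1.36), and Penk, encoding enkephalin, was 13.8 against 13.9 CPM (-0.02, interval -0.22 to 0.18). In the opioid system list, Pnoc, encoding nociceptin, and its receptor gene Oprl1 were lower (-0.68 and -0.81), within a list median of -0.12 (length-matched percentile 24.0). Genes of synaptic receptors were higher for 19 of 22 members, median 0.24 (length-matched percentile 87.2), among them the AMPA receptor subunit gene Gria1 (0.39) and the GABA-A subunit gene Gabra5 (0.53).

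The remaining lists in septal GABAergic neurons of chronic morphine against saline were as follows. Heat shock genes were lower for 11 of 13 members, median -0.53 (length-matched percentile 25.3), with the chaperone genes Hspa8 at 64.2 against 152 CPM and Hsp90aa1 at 107 against 192 CPM. Cholesterol synthesis genes were lower for 14 of 14 members (median -0.41, length-matched percentile 6.71). Cyclic AMP and protein kinase A genes had 15 of 25 members higher, median 0.04 (percentile 22.2), with the kinase inhibitor gene Pkia higher (0.52) and the G protein gene Gnas lower (-0.65). Medians were -0.07 for glucocorticoid-responsive genes (percentile 85.0), -0.07 for septal neuromodulator receptor genes (percentile 38.4), in which the oestrogen receptor gene Esr1 was 24.0 against 15.3 CPM, and -0.19 for circadian genes (percentile 22.5). Genes of other cell types had medians of -0.66 for myelin (percentile 0.06), -0.82 for microglia and inflammation (percentile 3.62) and 0.13 for reactive astrocytes (percentile 71.8). The myelin genes are markers of free RNA in neurons, whose estimated share was 6.16% of UMIs in saline and 4.83% in chronic morphine.

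The highest genes of chronic morphine against saline were mostly antisense or overlapping genes. Dnm3os, which lies inside Dnm3 on the opposite strand, was 30.4 against 7.46 CPM (log2 ratio 2.02, interval 1.81 to 2.24), followed by Pip5k1bos (1.95), Chmp4c (1.88), Csmd2os (1.81), Ccr9 (1.80) and St8sia3os (1.76). Each of these shares its position with another gene on the opposite strand, so which gene gave the UMIs is uncertain. The lowest included the tubulin genes Tubb4b (-1.77) and Tubb2a (-1.73), the respiratory chain gene Cox4i1 (-1.63) and the brain creatine kinase gene Ckb (-1.63), all short genes. With median-of-ratios scaling every log2 ratio of this comparison was higher by 0.14, so negative list medians smaller than that, those of the glucocorticoid, opioid and neuromodulator receptor lists, have no settled direction.

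**Figure D1:**
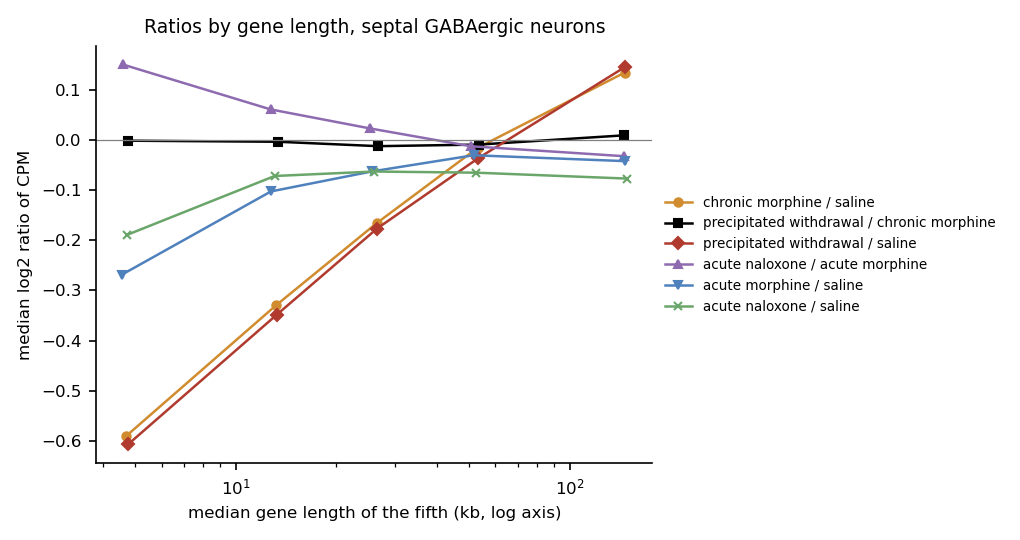
Median log2 ratio of genes (vertical axis) in 5 groups of genes by length (horizontal axis, median length of the group in kilobases, log scale), for septal GABAergic neurons in each comparison. Against saline the chronic morphine and withdrawal libraries run from -0.59 and -0.61 in the shortest group to 0.13 and 0.15 in the longest, and withdrawal against chronic morphine lies between -0.01 and 0.01.

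The rapid immediate early genes were lower by more in neurotensin neurons than in the pooled other septal neurons. Within septal GABAergic neurons, 22 sub-clusters had enough nuclei in every library, and the pair with Nts among its 10 leading genes is called the Nts sub-clusters here. In them the rapid immediate early genes summed to 485 CPM in chronic morphine against 1158 in saline (log2 ratio -1.26, interval -1.34 to -1.17), and in the other septal neurons to 413 against 517 CPM (-0.33, interval -0.36 to -0.29). Fos was 9.12 against 49.4 CPM in the Nts sub-clusters (-2.42, interval -3.03 to -1.89), and Junb 55.3 against 178 CPM (-1.68, interval -1.92 to -1.45). Nts itself, one of the genes that define them, was 237 against 482 CPM (-1.02, interval -1.15 to -0.90), and Oprm1 was 58.4 against 50.2 CPM (0.22, interval -0.08 to 0.52). The summed rapid list was lower in 22 of 22 sub-clusters, from -1.34 in the sub-cluster led by Il1rapl2, Etv1 and Nts to -0.13 in one led by Pde1c, Tacr1 and Dach1, and Oprm1 was higher in 20 of 22. For the sum of Fos, Fosb, Junb, Egr1, Arc, Npas4 and Nr4a1, and for the list without Homer1, a gene singled out after its values were seen, the lowest sub-cluster was not an Nts one but one led by Pdzrn3, Klhl1 and Slc26a4, at -1.76 and -1.66.

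**Figure D2:**
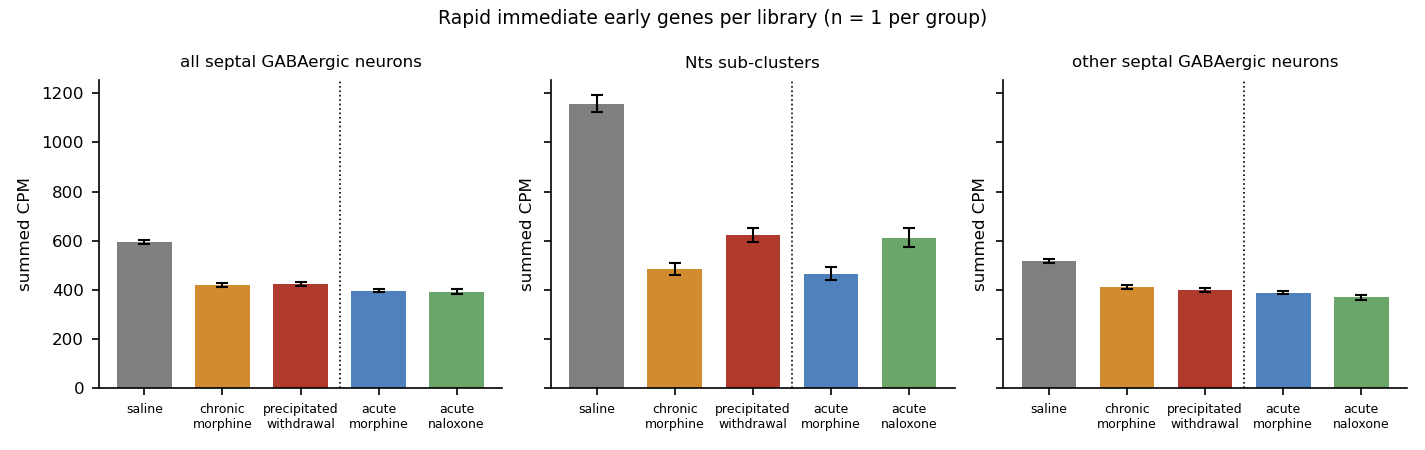
Summed CPM of the rapid immediate early genes (vertical axis) in each library (horizontal axis) for all septal GABAergic neurons, the Nts sub-clusters and the other septal GABAergic neurons; bars are 1 library each, error bars are 95% Poisson intervals, and the dotted line separates the libraries of different chemistry. The Nts sub-clusters of saline stand at 1158 CPM, above those of the other 4 libraries, which lie between 466 and 622 CPM.

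Shares of nuclei with an activity gene UMI gave the same order for chronic morphine and saline. After thinning each nucleus to 1000 UMIs, which left out none, 11.97% of septal GABAergic neurons in saline (95% exact binomial interval 11.0 to 12.9) had a UMI of Fos, Fosb, Junb, Egr1, Arc, Npas4 or Nr4a1, and 7.82% (7.06 to 8.64) in chronic morphine. The shares were 7.63%, 7.75% and 9.34% in withdrawal, acute morphine and acute naloxone, and unthinned they were 45.1%, 35.4%, 34.9%, 34.1% and 29.6% in the order of the groups. Oligodendrocytes gave 7.51%, 5.87%, 7.00%, 2.46% and 3.69% after the same thinning (median depths of 1681.5, 1592, 1489, 1720 and 1408.5 UMIs), and astrocytes 7.03%, 3.80%, 6.81%, 3.06% and 2.78% (2055, 2061, 1882, 1965.5 and 1453 UMIs). Free RNA weighs more in such shallow nuclei, as its estimated share in chronic morphine was 4.83% in septal neurons and 17.8% in astrocytes, so these shares are an upper guide to the neurons' background. In the Nts sub-clusters the thinned shares were 26.6%, 12.7%, 12.1%, 13.8% and 19.7%. A UMI of Fos itself was in 1.30%, 0.637%, 0.556%, 0.417% and 0.443% of septal neurons after thinning (6.03%, 2.90%, 2.57%, 2.19% and 2.30% unthinned) and in 0.740%, 0.427%, 0.769%, 0.145% and 0.230% of oligodendrocytes. A UMI of Nts was in 6.36%, 3.54%, 4.38%, 3.42% and 2.90% of septal neurons after thinning (18.2%, 14.0%, 13.9%, 11.0% and 8.89% unthinned) and in 3.07%, 0.854%, 1.196%, 0.434% and 0.922% of oligodendrocytes.

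In the other classes, chronic morphine against saline showed the same gain with gene length, and lists are set against length-matched random lists here too. Synaptic receptor genes in Slc17a6 glutamatergic neurons were higher for 19 of 22 members, median log2 ratio 0.35 (percentile 99.2). Glucocorticoid-responsive genes were higher for 6 of 7 members in oligodendrocyte precursors, median 0.54 (percentile 99.99), and for 10 of 16 in oligodendrocytes, median 0.10 (percentile 99.45). In astrocytes glucocorticoid-responsive genes were lower for 14 of 17 members, median -0.55 (percentile 6.42). Fkbp5, a member chosen after its values were seen, was higher there at 320 against 174 CPM (0.88, interval 0.72 to 1.03). Synaptic receptor genes in oligodendrocytes were lower for 11 of 16 members, median -0.34 (percentile 0.00), although their summed level was 2941 against 2670 CPM.

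Precipitated withdrawal against chronic morphine asks what naloxone did after the same morphine course. The libraries differed by that injection and the hour that followed it, and also by the pool of mice and its dissection. Neurons resembling striatal projection neurons were 4.60% against 2.02% of nuclei. In septal GABAergic neurons the rapid immediate early genes were at the same summed level, 423 against 421 CPM (log2 ratio 0.01, interval -0.03 to 0.04), with 10 of 24 measured members higher. Free RNA was not equal, since empty droplets of withdrawal held 55.7 against 33.5 CPM of Fos and 166 against 121 CPM of Egr1, and subtracting the profile of empty droplets left the summed log2 ratio at -0.02 and that of Fos at -0.78. Before subtraction, Fos was 4.41 against 5.22 CPM (-0.24, interval -0.59 to 0.10), Junb was 22.2 against 23.3 CPM (-0.07, interval -0.22 to 0.09), and Npas4, an activity-specific transcription factor gene, was lower at 4.48 against 8.25 CPM (-0.88, interval -1.20 to -0.57). Nts was 59.0 against 45.7 CPM (0.37, interval 0.27 to 0.47), 0.53 in female and 0.03 in male nuclei, and Oprm1 was 82.2 against 71.0 CPM (0.21, interval 0.13 to 0.30). The median ratio of genes showed no trend with gene length, lying between -0.01 and 0.01 in each of the 5 length groups.

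Among the lists in septal GABAergic neurons of withdrawal against chronic morphine, 4 lay above percentile 97 of length-matched random lists, at small sizes. Glucocorticoid-responsive genes were higher for 15 of 18 members, median 0.20 (length-matched percentile 99.97), with a sum of 410 against 362 CPM (0.18, interval 0.14 to 0.22). Cholesterol synthesis genes were higher for 11 of 14, median 0.17 (percentile 99.95). Late activity genes were higher for 15 of 20, median 0.12 (percentile 99.34), with the synaptic organiser Nptx2 at 2.08 against 0.875 CPM (1.24, interval 0.57 to 1.95) and the chromatin remodeller gene Baz1a at 11.7 against 6.13 CPM (0.93, interval 0.67 to 1.19). Septal peptide genes were higher for 7 of 10, median 0.16 (percentile 97.6), including Tac1, encoding substance P (0.69, interval 0.40 to 0.99). Cyclic AMP genes were not among these 4, with 13 of 25 higher and a median of 0.01 (percentile 84.7), and included the phosphodiesterase gene Pde10a at 946 against 661 CPM (0.52, interval 0.49 to 0.54). Pde10a and Tac1 are also expressed by striatal projection neurons, which were more frequent in the withdrawal library. Pde10a in those neurons was 791 CPM, below the septal 946 CPM in that library. Admixture at that level would not by itself give 946 CPM.

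The remaining lists of this comparison also lay within the central 95% of length-matched random lists. Heat shock genes were lower for 8 of 12 members, median -0.10 (length-matched percentile 5.05), and synaptic receptor genes for 15 of 22, median -0.04 (percentile 11.97). Opioid system genes had 12 of 18 higher, median 0.03 (percentile 81.1), and neuromodulator receptor genes 11 of 20, median 0.03, with the galanin receptor gene Galr1 (0.55) and the somatostatin receptor gene Sstr2 (0.45) among the largest. Circadian genes had 9 of 17 lower, median -0.06, with Rorb at 0.81. Medians were -0.02 for myelin, 0.08 for reactive astrocyte and -0.13 for microglia and inflammation genes. The highest single genes were the folate receptor gene Folr2 (45.5 against 21.3 CPM, log2 ratio 1.09, interval 0.96 to 1.23), Mir670hg (0.75) and Nmnat2, an axon survival enzyme (338 against 206 CPM, 0.71, interval 0.67 to 0.76). Folr2 and Nmnat2 each overlap a gene model on the other strand. The lowest were Zbbx (-0.59), Nox4 (-0.51), the potassium channel subunit gene Kcnmb2 (-0.47) and Ndst4 (-0.46).

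In the Nts sub-clusters the rapid immediate early genes summed to 622 CPM in withdrawal against 485 in chronic morphine (log2 ratio 0.36, interval 0.26 to 0.45), and in the other septal neurons to 398 against 413 CPM (-0.05, interval -0.09 to -0.01). Most of the difference came from Homer1, a synaptic scaffold gene singled out after its values were seen, at 265 against 163 CPM (0.70, interval 0.55 to 0.86); without it the sum was 357 against 322 CPM (0.15, interval 0.03 to 0.27). The 7 classical genes, Fos and Junb among them, summed to 145 against 147 CPM (-0.02, interval -0.21 to 0.16). Nts, a defining gene of these sub-clusters, was 327 against 237 CPM (0.46, interval 0.33 to 0.60), and the glucocorticoid-induced chaperone gene Fkbp5 was 129 against 98.0 CPM (0.40, interval 0.19 to 0.61). Over all 22 sub-clusters the summed rapid list ranged from -0.69 to 0.93 and was higher in 9, and Fkbp5 was higher in 15.

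Astrocytes carried the largest list difference between withdrawal and chronic morphine. Cholesterol synthesis genes were higher for 13 of 13 measured members, median log2 ratio 0.76 (above all 10000 length-matched random lists), and summed to 1306 against 761 CPM (0.78, interval 0.70 to 0.86). Saline lay between them at 1065 CPM. The log2 ratio of this sum to saline was 0.29 (interval 0.23 to 0.36) in withdrawal and -0.48 (interval -0.57 to -0.40) in chronic morphine. Glucocorticoid-responsive genes were higher for 17 of 19, median 0.31 (percentile 99.99), and summed to 2960 against 2334 CPM (0.34, interval 0.30 to 0.39). Against saline, at 2832 CPM, the same sum was 0.06 (interval 0.02 to 0.11) in withdrawal and -0.28 (interval -0.33 to -0.23) in chronic morphine. Genes of both lists, named after their values were seen, included Hmgcs1 in sterol synthesis at 102 against 42.0 CPM (1.27, interval 0.95 to 1.61) and Fkbp5 at 640 against 320 CPM (1.00, interval 0.88 to 1.12). After thinning to 1000 UMIs, 44.7% of astrocytes in withdrawal had an Fkbp5 UMI and 24.0% in chronic morphine (63.1% and 39.2% unthinned), against 14.9%, 18.5% and 19.03% in saline, acute morphine and acute naloxone. In oligodendrocytes, which also express Fkbp5, the thinned shares were 41.4% and 35.0%.

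The phosphodiesterase genes Pde10a, Pde7b and Pde4d and the choroid plexus gene Ttr also differed in astrocytes between withdrawal and chronic morphine. Pde10a was 2398 against 415 CPM (log2 ratio 2.53, interval 2.44 to 2.62), Pde7b was 1302 against 489 CPM (1.41, interval 1.32 to 1.51) and Pde4d was 1082 against 448 CPM (1.27, interval 1.18 to 1.37). Pde7b and Pde4d were named after their values were seen, and other phosphodiesterase genes are not given here. Ttr, encoding the choroid plexus carrier transthyretin, was 198 against 2.77 CPM (6.06, interval 5.10 to 7.48), 7.29 in female and 2.67 in male nuclei, with 577 of its 612 UMIs in withdrawal from female nuclei of 1 of the 2 astrocyte clusters. In that cluster Enpp2 had 166 UMIs in withdrawal and 12 in chronic morphine, and the choroid plexus marker Kl had 5 and 0. Enpp2 had 66 and 51 UMIs in the other astrocyte cluster. Enpp2 and Kl were chosen after their values were seen. The Ttr difference may therefore come from choroid plexus nuclei within that cluster rather than from astrocytes, which was not tested. Dapk2 was higher (2.26, interval 1.74 to 2.85), and Adamts18 (-1.76), Klf8 (-1.48) and Pipox (-1.29) were the lowest. Circadian genes were higher for 14 of 17 members (median 0.17, length-matched percentile 99.58). In the other glia, late activity genes were higher for 8 of 8 members in oligodendrocytes (median 0.36, percentile 99.81), and synaptic receptor genes were lower for 17 of 21 in oligodendrocyte precursors (median -0.27, percentile 0.00). Clustering at resolution 2, unlike resolution 1, split off nuclei with precursor leading genes that scored highest for septal neurons. Their mean doublet score was 0.22 and their median depth 9228.5 UMIs. They numbered 11 in chronic morphine and 6 in withdrawal, and their part in the lower synaptic receptor genes was not tested.

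**Figure D3:**
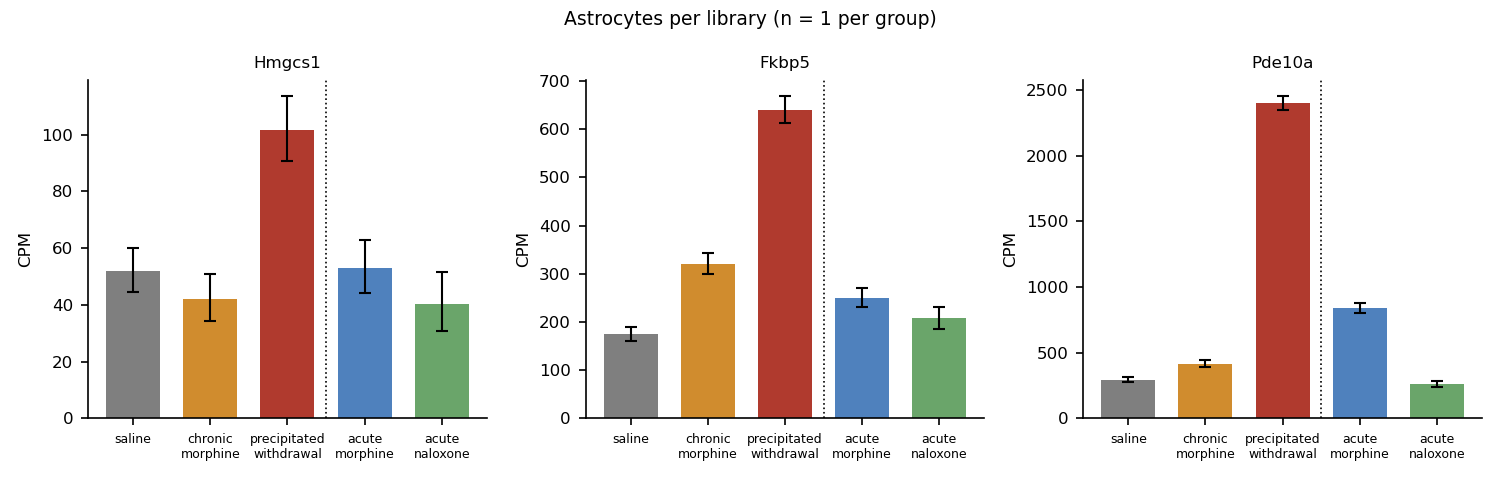
CPM of Hmgcs1, Fkbp5 and Pde10a (vertical axes, different scales) in astrocytes of each library (horizontal axis); bars are 1 library each, error bars are 95% Poisson intervals, and the dotted line separates the libraries of different chemistry. The withdrawal library is the highest of the 5 for all 3 genes, at 102, 640 and 2398 CPM.

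Precipitated withdrawal against saline asks how the withdrawal state differs from no drug, and it shares the saline library with the first comparison. In septal GABAergic neurons rapid immediate early genes were lower for 24 of 25 measured members, median log2 ratio -0.83 (length-matched percentile 0.28), and their sum was 423 against 595 CPM (-0.49, interval -0.53 to -0.46). Junb was 22.2 against 59.3 CPM (-1.41, interval -1.55 to -1.28), Npas4 was 4.48 against 11.2 CPM (-1.32, interval -1.63 to -1.02), and Fos was 4.41 against 12.9 CPM (-1.55, interval -1.86 to -1.25, and -2.37 after free RNA of the empty droplets was subtracted). Nts was 59.0 against 103 CPM (-0.81, interval -0.90 to -0.72), Oprm1 was 82.2 against 51.9 CPM (0.67, interval 0.57 to 0.76), and Penk was 13.7 against 13.9 CPM (-0.02, interval -0.23 to 0.18). In the Nts sub-clusters the rapid list was lower by more (-0.90, interval -0.97 to -0.82) than in the other septal neurons (-0.38, interval -0.42 to -0.34), while Homer1 there was 0.14 (interval 0.00 to 0.28).

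Other lists of withdrawal against saline in septal GABAergic neurons ranged from higher to lower. Glucocorticoid-responsive genes had a median of 0.16 (length-matched percentile 98.96), late activity genes 0.11 (percentile 90.4) and synaptic receptor genes 0.18 (percentile 63.6). Septal peptide genes had a median of -0.70 (percentile 16.1), heat shock genes -0.63 (percentile 12.6) and cholesterol synthesis genes -0.31 (percentile 38.5). Cyclic AMP genes had a median of 0.03. Opioid system, neuromodulator receptor and circadian genes had medians of -0.11, -0.11 and -0.12, without a settled direction, since median-of-ratios scaling added 0.16 in this comparison. Medians were -0.66 for myelin, 0.23 for reactive astrocyte and -0.90 for microglia and inflammation genes. The highest genes were Serpind1 (20.0 against 3.90 CPM, log2 ratio 2.36), Pip5k1bos (2.24), Dnm3os (2.11), Ckmt2 (2.07) and Folr2 (2.06), each overlapping another gene on the opposite strand. The lowest were Isyna1 (-2.01), Fbxl6 (-1.98), Haghl (-1.89) and the cytochrome gene Cyc1 (-1.76). In astrocytes cholesterol synthesis genes were higher for 10 of 13 members, median 0.38 (above all length-matched random lists), and summed to 1306 against 1065 CPM (0.29, interval 0.23 to 0.36). The trend with gene length was that of chronic morphine, from -0.61 in the shortest group to 0.15 in the longest.

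Acute naloxone against acute morphine compares a single antagonist with a single agonist injection within the second pair of libraries. In septal GABAergic neurons the rapid immediate early genes summed to 393 against 398 CPM (log2 ratio -0.02, interval -0.06 to 0.03), but to 0.26 in female and -0.20 in male nuclei. Fos was 6.30 against 4.23 CPM (0.58, interval 0.17 to 0.98; 1.76 in female and -0.31 in male nuclei), Egr1 was 18.5 against 12.9 CPM (0.52, interval 0.29 to 0.75), and the nuclear receptor gene Nr4a2 was 0.748 against 2.64 CPM (-1.77, interval -2.84 to -0.93; -2.70 in male nuclei). Oprm1 was 117 against 93.7 CPM (0.32, interval 0.23 to 0.41), Nts was 46.4 against 36.6 CPM (0.34, interval 0.20 to 0.48), and Penk, at 11.1 CPM in acute morphine, did not differ detectably at this depth (log2 ratio 0.11, interval -0.16 to 0.37, and -0.66 thinned to 1000 UMIs). The Nts sub-clusters held a higher rapid list, 613 against 466 CPM (0.40, interval 0.27 to 0.52), with Junb at 67.7 against 41.0 CPM (0.73, interval 0.33 to 1.12) and Nts, a defining gene, at 282 against 204 CPM (0.47, interval 0.29 to 0.65); the other septal neurons were at 370 against 389 CPM (-0.08, interval -0.12 to -0.03).

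Among the lists of acute naloxone against acute morphine in septal GABAergic neurons, heat shock genes were lower for 8 of 11 members, median -0.17 (below all length-matched random lists), with Hsph1 at 23.8 against 33.8 CPM (-0.51, interval -0.68 to -0.33). Circadian genes were lower for 11 of 18, median -0.13 (percentile 0.22). Myelin genes were higher for 10 of 12, median 0.36 (percentile 99.9), and the estimated share of free RNA in these neurons was 3.92% in acute naloxone and 2.89% in acute morphine. Medians were 0.08 for rapid immediate early genes, 0.04 for late activity, -0.02 for glucocorticoid-responsive, -0.05 for opioid system, -0.06 for cyclic AMP, 0.11 for septal peptide, -0.01 for neuromodulator receptor, 0.02 for synaptic receptor, 0.08 for cholesterol synthesis, 0.31 for reactive astrocyte and 0.22 for microglia and inflammation genes. The highest genes were the small noncoding RNA Bc1 (205 against 69.2 CPM, log2 ratio 1.57, interval 1.48 to 1.65), Cmss1 (1.14), the kinase gene Cdk8 (0.94) and the mitochondrial tRNA synthetase gene Lars2 (0.89), and Cdk8 was also among the 3 highest genes in each of the other 4 classes. The lowest were Stac2 (-0.63), the AMPA receptor accessory gene Cnih3 (-0.56) and Grm4 (-0.55). Mitochondrial UMIs in these neurons were 0.217% in acute naloxone and 0.119% in acute morphine.

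**Figure D4:**
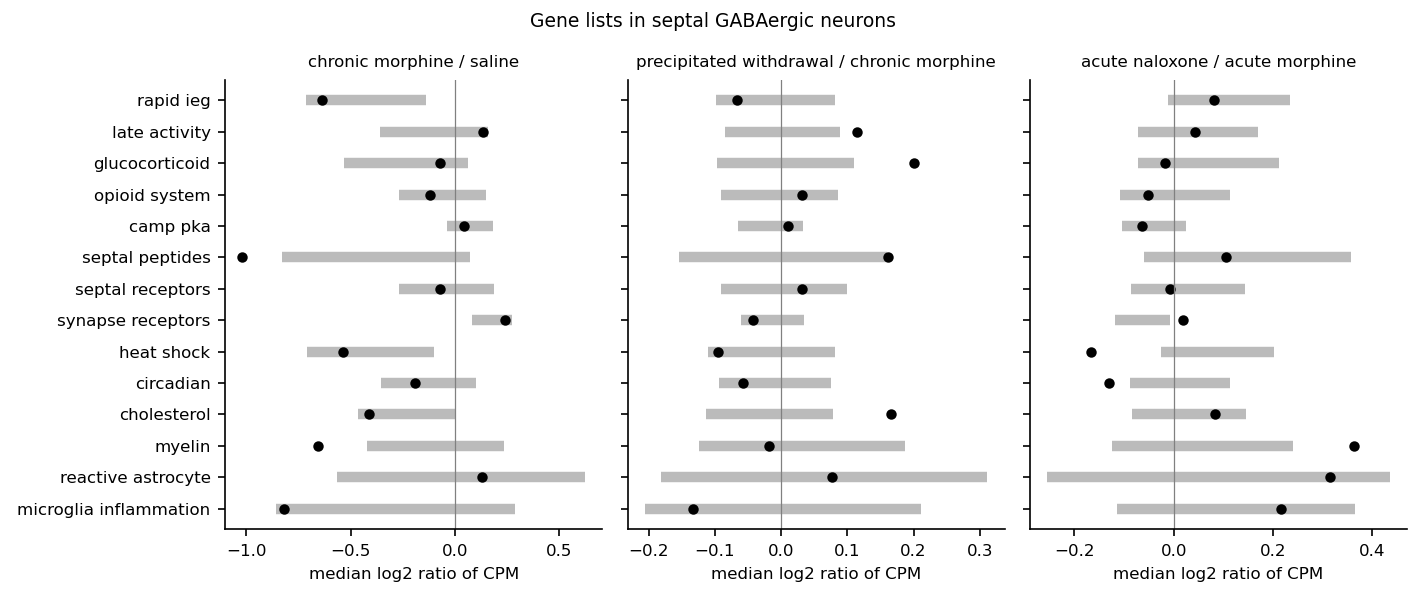
Median log2 ratio of each fixed gene list in septal GABAergic neurons (horizontal axis, different scale in each panel, points). Grey bars are the central 95% range of 10000 random lists matched on gene length and expression. Panels show chronic morphine against saline, withdrawal against chronic morphine, and acute naloxone against acute morphine. Glucocorticoid-responsive and cholesterol synthesis genes lie above that range for withdrawal against chronic morphine, at 0.20 and 0.17, as do late activity and septal peptide genes.

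Acute morphine and acute naloxone against saline are given side by side only, because the acute libraries differed from the saline library in chemistry, sequencer and software as well as in treatment, which cannot be told apart. In septal GABAergic neurons the rapid immediate early genes had log2 ratios of -0.58 (interval -0.62 to -0.55) and -0.60 (interval -0.64 to -0.56), and in the Nts sub-clusters of -1.31 and -0.92. Septal peptide genes had medians of -1.34 and -0.89. Oprm1 was 93.7 and 117 against 51.9 CPM. The most extreme genes were the same kind in both acute libraries: Schip1, a cytoskeletal adaptor gene, was at 1240 and 1217 CPM against 0.138 in saline, and Zbtb9 and Aldh4a1, without a UMI in saline, were at least 274-fold and at least 256-fold higher in acute morphine (3 counts in saline taken as the floor). Spag5 was 0.491 and 1.12 against 162 CPM, and the potassium channel gene Kcnq1 was 8.49 and 10.2 against 315 CPM. Kcnq1 overlaps Kcnq1ot1 and other genes on the opposite strand, so which gene gave its UMIs is uncertain. Ratios this far from 0 depend on a few UMIs: in acute morphine against saline the log2 ratio of Schip1 was 12.96, or 11.96 with 5 UMIs added, 11.73 in female and 14.75 in male nuclei, and that of Spag5 was -8.31, or -7.01 with ambient RNA subtracted and -9.07 in male nuclei. With 5 UMIs added Zbtb9 was at 7.37 and Aldh4a1 at 7.27. In acute naloxone against saline Schip1 was 12.93, or 11.93 with 5 UMIs added, and Spag5 was -7.13, or -5.49 with ambient RNA subtracted and -6.42 thinned to 1000 UMIs.

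Positions of the genes named most are given on GRCm38, the build of the tables (mm10), from GENCODE M21. Nts lies on chromosome 10 from 102481756 to 102490486, Oprm1 on chromosome 10 from 6758506 to 7038198, Fos on chromosome 12 from 85473890 to 85477273 and Junb on chromosome 8 from 84974484 to 84978718. Fkbp5 lies on chromosome 17 from 28399094 to 28517527, Pde10a on chromosome 17 from 8525372 to 8986648, Hmgcs1 on chromosome 13 from 119690379 to 119708260 and Ttr on chromosome 18 from 20665280 to 20674321. Their identifiers in the tables are, in that order, ENSMUSG00000019890, ENSMUSG00000000766, ENSMUSG00000021250, ENSMUSG00000052837, ENSMUSG00000024222, ENSMUSG00000023868, ENSMUSG00000093930 and ENSMUSG00000061808.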

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

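All 8 tests in this part were chosen after the pattern they address had been seen; what free RNA and gene length would show was written before those values were computed, and the other 6 tests, and the size of the sex difference that led to a mention, were chosen only after their results were seen.

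Nuclei called female and male, which apart from wrong calls come from different mice of the same pool, had log2 ratios at least 1 apart, with intervals on opposite sides of 0, in 3 of 1025 comparisons of named genes, summed lists and astrocyte Pde10a. Opposite directions that were closer or less precise, such as those of Fos between the acute libraries, are not among the 3. None of these differences was tested. Genes named as highest or lowest of a comparison had to share a direction in both sexes. They could not be among the 3 there, so the count is no measure of agreement between the sexes. Between acute naloxone and acute morphine, Npas4 in septal GABAergic neurons had a log2 ratio of 0.82 (interval 0.38 to 1.24) in female and -0.43 (interval -0.84 to -0.04) in male nuclei, a difference of 1.25. Pde10a in astrocytes had 0.33 in female and -3.92 in male nuclei, a difference of 4.24, with 91.2 CPM in male nuclei of acute naloxone and 1398 CPM in those of acute morphine. Against saline, Pde10a in astrocytes of acute naloxone had 0.48 in female and -1.41 in male nuclei, a difference of 1.89. Pde10a in astrocytes of acute morphine against saline had 0.15 (interval -0.04 to 0.35) in female and 2.51 (interval 2.29 to 2.75) in male nuclei, a wider difference that is not among the 3 because the directions were not opposite. Male nuclei of acute morphine therefore lay farther above saline than those of acute naloxone lay below it. Chemistry, sequencer and software of saline differed from those of both acute libraries. The values against saline therefore do not settle which acute library made the gap. Fkbp5 in astrocytes was not among the 1025 and was chosen after its values were seen. Against saline it had -0.44 (interval -0.72 to -0.17) in female and 1.44 (interval 1.08 to 1.82) in male nuclei of acute morphine, and -0.41 and 1.04 in those of acute naloxone.

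Among signals outside the comparisons, 2 that stood above saline are described here, and they were not the only ones. An unnamed cluster led by Rpl13a, Tuba1a and Bc1 held 4.57% of the acute naloxone nuclei (exact binomial interval 4.10 to 5.08), 328 nuclei against 2 in saline, with a median of 1363.5 UMIs and 1.28% mitochondrial UMIs. Ttr in empty droplets was higher than in saline by log2 ratios of 2.42 (interval 2.22 to 2.64) in withdrawal, 0.92 (interval 0.66 to 1.18) in acute morphine and 0.66 (interval 0.38 to 0.94) in acute naloxone. Other genes chosen after their values were seen also stood above saline in empty droplets, among them Fosb at 20.4 against 3.17 CPM and Nr4a3 at 17.1 against 5.39 CPM in withdrawal, and Glp1r at 85.5 CPM in acute morphine and 63.9 CPM in acute naloxone against 2.85 CPM.

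Rapid immediate early genes were lower in septal GABAergic neurons of chronic morphine than of saline. Free RNA as the whole cause is argued against by a log2 ratio of -0.52 (interval -0.55 to -0.48) after subtraction of the empty-droplet profile. A shift of the whole library, alike in every kind of septal neuron, is argued against by -1.26 (interval -1.34 to -1.17) in the Nts sub-clusters, where the ratios of the other septal neurons would give -0.43. Gene length as the cause is not argued against in this comparison. The list median lay at percentile 9.59 of length-matched random lists, within what was written beforehand for gene length. Against saline the list lay lower among such lists in withdrawal, at percentile 0.28, with the same length trend. It lay at 1.29 and 0.20 in the acute libraries, where the shortest genes were at only -0.27 and -0.19. All of these percentiles rest on the same saline library, so they are not independent evidence against gene length. Length alone would not set the Nts sub-clusters apart from the pooled other septal neurons. Saline stood above all 4 other libraries: the list's log2 ratio to saline was also -0.49 in withdrawal and -0.58 and -0.60 in the acute libraries, which had no morphine course, and the shortest genes were at -0.59 and -0.61 against saline in chronic morphine and withdrawal. Saline having been prepared or counted differently therefore stays open, as do the treatment and individual mice, none of them tested, since each group has 1 library.

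Cholesterol synthesis genes, Pde10a and Fkbp5 were higher in astrocytes of withdrawal than of chronic morphine. RNA or nuclei of striatal projection neurons as the cause of the Pde10a difference are argued against by its levels in withdrawal. Pde10a was 2398 CPM in astrocytes and 791 CPM in striatal projection neurons, so admixture at that level would not by itself give 2398 CPM. The other 7 striatal markers differed by 0.704 CPM in sum (normal-approximation interval -16.3 to 17.7), where 3973 CPM was set as needed. Admixture could not have reached that sum either, so the marker test could have only 1 outcome and adds no evidence. The markers show only no rise beyond counting error. Choroid plexus nuclei in the astrocyte cluster led by Synpo2 and Apoe, as the whole cause of these differences, are argued against by the other astrocyte cluster. There the smallest of the 3 log2 ratios was 0.76 (interval 0.68 to 0.85). The presence of such nuclei in the first cluster, which held most Ttr UMIs of withdrawal, is not argued against. Mice of 1 sex alone are argued against by a smallest ratio of 0.59 (interval 0.44 to 0.74) over both sexes. Astrocytes of another region through a different dissection could still contribute, as could individual mice, given how Pde10a and Fkbp5 varied between sexes in the acute libraries; neither was tested, nor was the naloxone treatment.

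The 8 highest and 8 lowest genes of acute morphine against saline reached ratios such as that of Schip1, with 32853 UMIs against 4. A difference in gene annotation or counting software is consistent with 15 of these 16 genes differing at least 4-fold, in 1 direction, between each acute library and each of the other 3 libraries. An effect of the morphine injection is argued against by only 1 of 16 genes differing at least 2-fold between the acute libraries. Chemistry and sequencer differ between the same libraries and cannot be told apart from the software.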

How the results depend on the processing

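Ambient RNA from empty droplets, Malat1 left out, the 4 sub-clusters kept, length-matched lists and the astrocyte sums were chosen only after the results were seen. No paired analysis was possible because each group has 1 library of pooled mice, and no result rests on a test.

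Of 8 summed lists under 110 alternative values, 90 stayed within the counting interval of the reported value, 20 lay outside and 103 kept the direction; the 4 sums that differed by at least 0.5 with their intervals clear of 0 kept it in 55 of 55. For named genes, 5647 of 6295 values stayed within the interval, 624 lay outside and 24 reversed a called direction. For list medians 153 of 168 stayed within and 160 kept the direction. Of 140 class shares 69 and of 70 activity shares 68 lay outside their intervals. Ambient subtraction gave values for 413 genes with the first profile and 411 with that of empty droplets; the rest had 3 or fewer counts left.

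The cause of the following was not tested. The log2 ratio of the summed rapid immediate early genes in septal GABAergic neurons was, with median-of-ratios scaling, -0.36 for chronic morphine against saline, -0.33 for withdrawal against saline, -0.51 for acute morphine against saline and -0.54 for acute naloxone against saline. In female nuclei it was -0.44 for chronic morphine against saline, -0.035 for withdrawal against chronic morphine, 0.26 for acute naloxone against acute morphine, -0.63 for acute morphine against saline and -0.37 for acute naloxone against saline. In male nuclei it was -0.20 for acute naloxone against acute morphine, -0.45 for acute morphine against saline and -0.65 for acute naloxone against saline. For withdrawal against saline it was -0.46 thinned to 1000 UMIs and -0.54 with the ambient RNA of empty droplets subtracted.

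In astrocytes of withdrawal against chronic morphine the summed cholesterol synthesis genes were 0.95 in female and 0.59 in male nuclei, and the summed glucocorticoid-responsive genes were 0.24 in female nuclei, 0.49 in male nuclei, 0.29 with at least 2000 UMIs and 0.42 with clusters weighted equally.

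Single genes of the septal class reversed as follows. With ambient RNA subtracted, Hspa1a was 1.196 and Mal 0.21 for chronic morphine against saline, Hspa1a 0.37 and Dbp 0.17 for acute morphine against saline, Dbp 0.25 for acute naloxone against saline, and Mt1 -2.44 and Apoe -2.32 for acute naloxone against acute morphine. With that of empty droplets, Tsc22d3 was 0.44 for chronic morphine against saline, Mt2 -0.36 for acute naloxone against acute morphine, Dbp 0.10 and Aspa 0.064 for acute morphine against saline, and Dbp 0.19 for acute naloxone against saline. Thinned to 1000 UMIs, Timp1 was -0.0070 for chronic morphine against saline and -0.13 for acute naloxone against saline, C4b 0.077 for withdrawal against chronic morphine, Spp1 0.022 for acute morphine against saline, and Pomc -0.35, Ntsr1 -0.027 and Dnajb1 0.089 for acute naloxone against acute morphine. In male nuclei C4b was 0.17 for chronic morphine against saline, and Fos -0.31 and Ntsr1 -0.28 for acute naloxone against acute morphine. In female nuclei Tac2 was 0.27 for withdrawal against saline. With the 4 sub-clusters kept, Tac1 was 0.24 for acute naloxone against acute morphine.

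Depth and a size rule limit which single genes are called. A call needed an interval clear of 0 and a log2 ratio of at least 0.5 in either direction. In data simulated with counting error alone, a 1.5-fold difference, not far above that size, was called for 73.1% of genes and a 2-fold one for 98.5%. The simulation held no variation between libraries or mice, so these rates describe counting error and the size rule only.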

Other observations

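The lists in this part were fixed beforehand, and the lists, classes and genes picked from them here were chosen only after the results were seen; no explanation was tested.

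In oligodendrocytes of withdrawal against chronic morphine, the late activity genes summed to 1929 against 1624 CPM (log2 ratio 0.25, interval 0.18 to 0.32), with the potassium channel gene Kcna1 at 600 against 439 CPM and the cell cycle inhibitor gene Cdkn1a at 34.4 against 19.5 CPM. In oligodendrocyte precursors the synaptic receptor genes summed to 7949 against 9199 CPM, with the NMDA receptor subunit genes Grin2a and Grin2b at log2 ratios of -1.51 and -0.88 and the AMPA receptor subunit gene Gria1 at -0.56. Nuclei with precursor genes and a high doublet score, separate only at resolution 2, were 11 in chronic morphine and 6 in withdrawal. Their part in these values was not tested. In Slc17a6 glutamatergic neurons opioid system genes were higher for 9 of 11 members, median 0.21 (length-matched percentile 99.6).

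In oligodendrocyte precursors of chronic morphine against saline, glucocorticoid-responsive genes summed to 1245 against 875 CPM (log2 ratio 0.51, interval 0.38 to 0.63), and myelin genes were lower for 6 of 7 members, median -1.32 (length-matched percentile 0.00). In astrocytes of acute naloxone against acute morphine, glucocorticoid-responsive genes were lower for 12 of 16 members, median -0.21 (length-matched percentile 0.02), but their sum differed by a log2 ratio of only -0.075 (interval -0.13 to -0.02), 0.04 (interval -0.06 to 0.13) in female and -0.15 in male nuclei. Median-of-ratios scaling added 0.10 to every log2 ratio of astrocytes in acute naloxone against saline.

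Malat1, a nuclear RNA, took 5.88%, 3.82%, 4.21%, 6.68% and 7.29% of UMIs of septal GABAergic neurons in saline, chronic morphine, withdrawal, acute morphine and acute naloxone. Estimated free RNA in astrocytes was 17.4%, 17.8%, 14.99%, 9.22% and 11.6% in the same order.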
